A study of Solanum lycopersicum with 6 samples.

How the data were processed

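Total RNA was isolated with TRIzol from embryos 21 days after flowering and small RNA libraries were built with a NEBNext small RNA kit, per the labels' protocols. Plants of the Micro-Tom cultivar grew under 16 h light at 26 °C and 8 h dark at 22 °C, per the labels. There were 3 WT and 3 nrpd1 libraries, and the labels assign all libraries of a genotype to 1 shared table. Bowtie is named in the submitters' processing notes, and its version, read trimming and the alignment settings are not given in the sources used here. The tables are ShortStack locus lists, per the labels and the file headers, with ShortStack's version and settings not given in the sources used here. Chromosome names in the tables give the build as SL4.0.

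Each table lists loci called in the pooled reads of 1 genotype. The read counts per locus (total, uniquely mapped, of the most abundant RNA, and by length from 20 to 24 nt with shorter and longer reads apart) are raw, per the file headers. The deposited RPM values are those counts on a reads-per-million scale relative to the mapped reads of the pool, so the number of mapped reads followed from the constant quotient of reads and RPM, 30.1 M for WT and 20.1 M for nrpd1. A deposited fraction column gives the number of distinct RNAs per read of a locus, and a strand column names loci with reads mainly from 1 strand. The phase score and the Dicer call (the read length that dominates a locus, or N where none does) are ShortStack's own, per the file headers. Other deposited columns give the length of each locus and of its leading RNA in bases. The lowest listed abundance was 0.532 RPM (16 reads) in WT and 0.548 RPM (11 reads) in nrpd1. An unlisted region was therefore counted at 15 reads in WT or 10 reads in nrpd1. Its fold is a lower bound only if it held no more reads than that, which could not be checked without the calling settings. In sums of reads by length over loci or regions, an unlisted region added no reads.

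How pooling and calling affect the values follows from these steps. Pooling hides the spread between libraries, so no count model was fitted and nothing was tested for significance. Loci were called separately per genotype at different depths, whose effect on the numbers of loci was not tested, and covered length and mean RPM per kb are given beside them. Multi-mapping reads are placed by the aligner, and the share of uniquely mapped reads was 78.0% in WT and 64.5% in nrpd1 loci. RPM is relative to all mapped reads, so a lower 24-nt class raises the RPM of every other class.

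Ratios are nrpd1 over WT of RPM, with 95% intervals from the exact binomial distribution of reads given their total (Clopper-Pearson). Shares of loci carry exact binomial intervals. The WT and nrpd1 loci were merged into 181895 regions where they overlapped by at least 1 base, and a region was called lower or higher at a 4-fold difference whose interval excluded 1. A WT 24-nt locus counted as still listed when any nrpd1 locus overlapped it by at least 1 base, and chance overlap came from 100 circular shifts of the loci along the chromosomes (seed 1). The spread that counting error alone would give was drawn from the median ratio and each region's reads. Families of miRNAs were assigned where the leading RNA of a locus matched a mature sequence within 2 mismatches and 2 nt of offset over at least 18 nt, and their 20- to 22-nt reads were summed. For the families matched only in nrpd1 the median over families used the listing minimum for WT, and the values printed for them are those of the same region in WT. Positions were split into 1-Mb windows and into the 25% at each chromosome end and the rest, with chromosome lengths taken from the last listed base. Calls were tested on simulated data in which 200 regions were given a known fold, of which 8 made lower were listed in neither genotype and 192 entered the 173418 regions compared. There all 50 regions made 16-fold higher and none of 173226 unaltered regions were called, while 16 of 45 made 16-fold lower were called. All 3 regions with at least 10 RPM made 16-fold lower were called. Unaltered regions were drawn at a ratio of 1 with counting error only, so calls under a general fall of 24-nt RNAs were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

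The groups, comparisons, alternatives and the rule for named items were fixed before the data were examined. The rule takes each of 34 listed small RNA families with at least 10 RPM in either genotype, the 5 loci per genotype with Dicer call 24 and most 24-nt reads, the 5 lowest and 5 highest ratios among merged regions with at least 50 RPM in either genotype, and per genotype the 5 loci with Dicer call 21, at least 10 RPM and the highest phase score. Alternatives covered scaling by miRNA reads, minimum abundance, overlap, fold threshold, merging distance, window size, the match to miRNA sequences and the chromosomes used. Planned comparisons of gene lists were not run, because the gene table at hand is on another assembly (SLM_r2.1) than the deposited loci. Planned count models, replicate blocks and left-out replicates were not run, because the tables used here hold 1 pooled value per genotype.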

Results

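Small RNAs were sequenced from tomato embryos of the dwarf cultivar Micro-Tom, collected 21 days after flowering, with 3 wild-type (WT) libraries and 3 libraries of the slnrpd1 mutant, called nrpd1 here. NRPD1 is the largest subunit of RNA polymerase IV, the plant polymerase that makes precursors of 24-nt small interfering RNAs (siRNAs), which guide DNA methylation. The libraries of each genotype had been pooled into 1 table of small RNA loci, so no replicate error could be computed and no difference was tested. Ratios compare these pooled libraries, not the genotypes at large, and the 95% counting intervals given cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The WT table rested on 30.1 M mapped reads, of which 66.2% lay in 177076 listed loci covering 47.1 Mb. The nrpd1 table rested on 20.1 M mapped reads, of which 49.9% lay in 93603 loci covering 19.3 Mb. Both tables list only loci of at least 0.5 RPM, the reads-per-million value relative to all mapped reads, so an unlisted locus need not be at 0. Messenger RNA of SlNRPD1 itself was not measured by these libraries, and which genes lie at the positions below was not analysed here.

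The first comparison asked which size classes of small RNA differed between mutant and WT embryos. The 24-nt class was the most abundant in WT, at 469576 RPM in listed loci, and it was 3.03-fold lower in nrpd1, at 154963 RPM. The 23-nt class was 2.33-fold lower, at 88310 RPM in WT and 37832 RPM in nrpd1. The 21-nt class, which includes most microRNAs (miRNAs) and phased siRNAs, was 4.42-fold higher in nrpd1, from 36225 to 160010 RPM, but scaling by miRNA reads in place of all mapped reads turned this to a ratio of 0.816. The 22-nt class was 2.79-fold higher, from 30302 to 84501 RPM, and its ratio was 0.515 when scaled by miRNA reads. Among reads in listed loci, 24-nt RNAs made up 71.0% in WT and 31.1% in nrpd1, while 21-nt RNAs made up 5.47% and 32.1%. The 20-nt class was 1.91-fold higher in nrpd1 by RPM and, like both other classes, lower under miRNA scaling. The counting interval of the nrpd1/WT ratio was 0.3296 to 0.3304 for 24 nt, 4.41 to 4.43 for 21 nt and 2.78 to 2.80 for 22 nt. The summed reads of the fixed miRNA families were 5.41-fold higher in nrpd1, a shift of 2.44 on the log2 scale, and relative to them 24-nt RNAs stood at 0.0610 of WT. Scaling by miRNA reads treats this sum as equal in both genotypes, which could not be tested here.

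**Figure D1:**
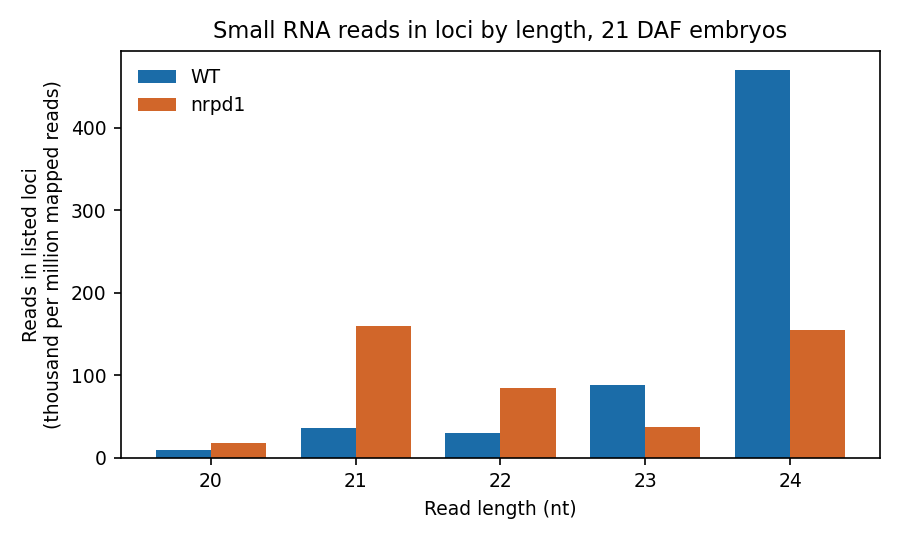
Reads in listed loci by read length (x axis, nt) in RPM (y axis, scaled by 1000), with 1 bar per genotype for the pooled libraries and no error bars because there is 1 table per genotype. The 24-nt bar stands at 469576 RPM in WT and 154963 RPM in nrpd1, and the 21-nt bar at 36225 RPM in WT and 160010 RPM in nrpd1, an order that turns to a ratio of 0.816 under scaling by miRNA reads.

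The next comparison asked how the loss of 24-nt RNAs was spread over their loci. WT embryos had 169411 loci whose reads were mainly 24 nt long by ShortStack's Dicer call, covering 45.0 Mb at a mean of 13.3 RPM per kb. The nrpd1 embryos had 79981 such loci covering 15.3 Mb at 11.7 RPM per kb. Loci under the listing minimum are not counted, and an effect of depth on these counts was not tested. At the WT 24-nt regions, 24-nt reads were 3.32-fold lower in nrpd1 and 23-nt reads 3.38-fold lower, while 21-nt reads were 1.21-fold and 22-nt reads 1.28-fold higher, the last pair being lower than WT once divided by the miRNA factor of 5.41. Regions unlisted in nrpd1 added no reads to these sums, so the falls are upper bounds and the rises lower bounds. The 5′ base of the leading RNA was A at 68.3% of WT and 69.0% of nrpd1 24-nt loci. Loci with reads on both strands made up 62.2% of the 24-nt loci in WT and 54.6% in nrpd1.

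Of the WT 24-nt loci, 78505 (46.3%, exact binomial interval 46.1 to 46.6) overlapped a locus listed in nrpd1, against a mean of 4.32% for 100 shifted placements of the nrpd1 loci. The share depended on abundance, reaching 88.3% of WT loci with at least 2 RPM and 99.8% of those with at least 10 RPM. The median WT abundance was 3.49 RPM at loci still listed in nrpd1 and 0.898 RPM at the others. A uniform reduction of all loci to a ratio of 0.307, followed by the listing minimum, would leave 45.3% listed. Where a WT 24-nt locus was still listed, the nrpd1 locus was again called 24 nt in 93.8% of cases. It had no Dicer call at 1743 loci and was called 23 nt at 1383 loci, 22 nt at 1044 loci and 21 nt at 692 loci. Conversely, 97.7% of the nrpd1 24-nt loci lay over a WT locus, and 1835 lay over none.

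Over the 11510 WT 24-nt regions with at least 10 RPM, the median nrpd1/WT ratio of 24-nt reads was 0.307, with an interquartile range of 0.256 to 0.362. Counting error alone would give 0.283 to 0.331. At 2607 of these regions (22.6%) 24-nt reads were at least 4-fold lower (98.8% under miRNA scaling), at 79 they were at least 2-fold higher (5 under miRNA scaling), and 23 were not listed in nrpd1. Across these regions the log2 RPM of both genotypes correlated (Pearson r = 0.82, Spearman rho = 0.81), with regions not being independent replicates.

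**Figure D2:**
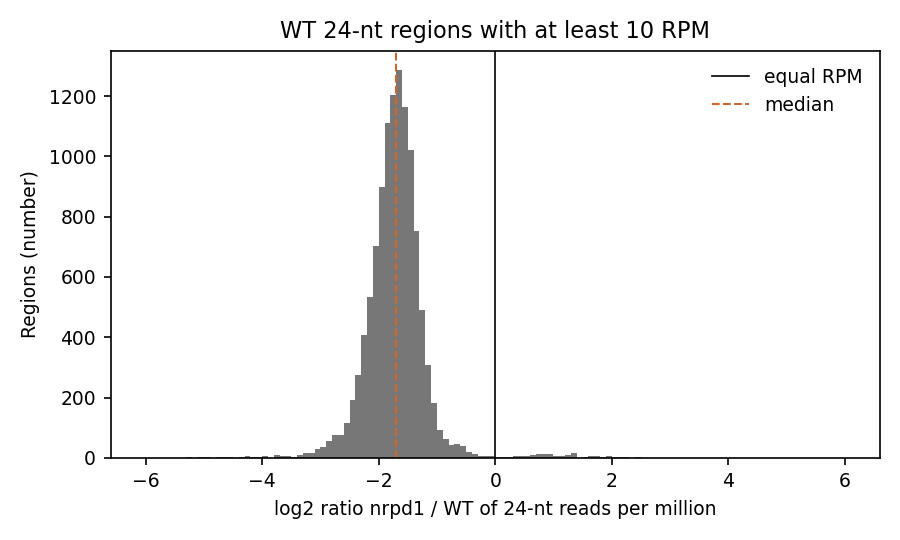
Histogram of the log2 ratio of 24-nt RPM, nrpd1 over WT (x axis), across WT 24-nt regions with at least 10 RPM (y axis, number of regions), with a solid line at equal abundance and a dashed line at the median. The median lies at -1.70, and 79 of 11510 regions lie at or beyond 2-fold higher in nrpd1, against 5 under miRNA scaling.

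Among single 24-nt loci some lay in this range and others stood apart. On chromosome 9 at 1649732–1650738 (all positions are on the SL4.0 build), 24-nt reads were at 573 RPM in WT and 189 RPM in nrpd1, a 3.03-fold difference, and 99.96% of the WT reads mapped uniquely. On chromosome 4 at 63126910–63127122 they were at 370 RPM in WT and 85.0 RPM in nrpd1, 4.36-fold lower. The other 3 WT loci with most 24-nt reads lay on unplaced sequence, called chromosome 0, where at most 28.4% of WT reads mapped uniquely. At 3668975–3710444 of that sequence 24-nt reads were 1.59-fold lower in nrpd1, at 5038204–5094864 they were 1.44-fold lower, and at 5505605–5550674 they were 1.55-fold lower. Among the 5 nrpd1 loci with most 24-nt reads, 3 had more of them than WT. The locus on chromosome 3 at 60690552–60691078 had 2.53 RPM of 24-nt reads in WT and 228 RPM in nrpd1, 90.1-fold higher. On chromosome 1 at 840798–841307 the values were 69.5 and 222 RPM, and on chromosome 8 at 1104184–1104463 they were 101 and 214 RPM. Under miRNA scaling the chromosome 1 and chromosome 8 loci had lower 24-nt values in nrpd1, since their ratios of 3.19 and 2.12 lie under the factor of 5.41.

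Merging the loci of both genotypes gave 181895 regions, and each was compared by its total RPM. In nrpd1, 21874 regions were at least 4-fold lower with a counting interval excluding 1. Of these 98.8% were 24-nt loci in WT, near the 95.9% of all regions listed in WT. Another 2502 regions were at least 4-fold higher, of which 674 were called 21 nt in nrpd1, 713 were called 22 nt, 438 were called 24 nt and 618 had no Dicer call. Of all called regions 89.7% were lower, and scaling by miRNA reads moved this to 99.9%, with 172843 lower and 192 higher. Of the lower regions 8248 were not listed in nrpd1, and of the higher regions 1151 were not listed in WT. Their folds are set against the listing minimum and are lower bounds only if no more reads lay there. In simulated data all 50 regions made 8-fold higher were called, but only 21 of 47 made 8-fold lower, so the count of lower regions leaves out many faint ones. The simulation held all other regions at a ratio of 1, so it does not show how many lower calls a uniform fall would give. Counting error alone around the median ratio of 0.307 gave a 5th percentile of 0.246 for 24-nt reads at strong regions (at least 10 RPM).

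Among the 1126 regions with at least 50 RPM in either genotype, 124 were at least 4-fold lower and 294 at least 4-fold higher in nrpd1 by RPM, against 624 lower and 62 higher under miRNA scaling. The 5 lowest ratios were all at 24-nt loci, the call of 95.9% of WT-listed regions of any abundance. The region on chromosome 8 at 1006384–1006638 went from 121 RPM in WT to 7.37 RPM in nrpd1, 16.4-fold lower, with only 11.9% of its WT reads mapping uniquely. The region on chromosome 4 at 7948297–7948542 was 13.1-fold lower, at 60.5 and 4.63 RPM, and that on chromosome 9 at 1964166–1964359 was 10.3-fold lower. The regions on chromosome 10 at 57645295–57645627 and on chromosome 2 at 42588703–42588966 were 9.82-fold and 9.29-fold lower.

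The 5 highest ratios stayed above the miRNA factor of 5.41 and belonged to loci whose nrpd1 reads were mainly 21 or 22 nt long. On chromosome 11 at 2753394–2754300 total reads stood at 0.565 RPM in WT, from 17 reads, and 211 RPM in nrpd1, a ratio of 373 with a counting interval of 233 to 641. On chromosome 2 at 27809079–27809634 the values were 1.23 and 352 RPM, 286-fold higher in nrpd1, where 43.9% of reads mapped uniquely. At 40649499–40650207 of chromosome 2 they were 6.88 and 1796 RPM, 261-fold higher. The region at 35033504–35033996 of chromosome 2 was not listed in WT and had 129 RPM in nrpd1, at least 260-fold higher. Only 19.2% of its nrpd1 reads mapped uniquely. The region on chromosome 1 at 74422362–74423707 was a 24-nt locus in WT with 20.4 RPM and a 22-nt locus in nrpd1 with 4327 RPM. Its 24-nt reads were also 35.9-fold higher, at 17.9 and 643 RPM.

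The abundance of miRNAs, which are cut from hairpin transcripts of RNA polymerase II, was compared over 34 small RNA families fixed beforehand. In 21 families the matched loci had at least 10 RPM in either genotype, and all 21 were higher in nrpd1 by RPM, 17 of them at least 4-fold, or 16 with loci unmatched or unlisted in WT counted in. The median log2 ratio was 3.75, or 13.5-fold (order-statistic interval over families 2.47 to 4.34), with families not being replicates. That median sets WT at the listing minimum for miR1919 and miR6027, which were matched only in nrpd1. With WT values of the same regions, as printed below, the median was 3.53, or 11.6-fold. The sum over the 27 families matched in either genotype, those under 10 RPM included, was 5760 RPM in WT and 31171 RPM in nrpd1. Of this miR159 alone made up 2334 and 12897 RPM. Scaled by that sum, miR162, miR166, miR319, miR394 and miR858 had lower values in nrpd1 than in WT and the other 16 families higher ones, although miR159, at 5.53 against 5.41, lay near the factor. Its ratio was 5.26 with WT reads unmatched in WT counted in and 8.03 over loci matched in either genotype. The factor is the summed ratio of the families themselves, so some had to lie on either side of it.

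Among families that target transcription factors, 8 of 12 passed the minimum, and all 8 were higher in nrpd1 by RPM. The family miR156, which targets SPL factors, stood at 37.1 RPM in WT and 907 RPM in nrpd1, 24.4-fold higher. Regulators of auxin response factors include miR160, at 1.13 and 27.3 RPM with a ratio of 24.1, and miR167, with a ratio of 8.56. With the 3 miR160 loci unlisted in WT counted at the listing minimum its ratio was 10.4 (8.19 to 13.3). It was 13.5 for miR396, which targets growth-regulating factors, and 5.53 for miR159, which targets GAMYB factors. The ratio was 4.70 for miR166 (3.29 over loci matched in either genotype), a regulator of class III HD-ZIP factors, 3.83 for the TCP regulator miR319 and 2.79 for the MYB regulator miR858, and under miRNA scaling these last 3 were lower in nrpd1.

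Of the 7 families that target disease resistance genes, 5 passed the minimum and were 6.39-fold to 33.9-fold higher in nrpd1, above the miRNA factor in each case. The family miR482 stood at 232 and 1942 RPM, 8.37-fold higher, and miR6022 at 71.3 and 1251 RPM, 17.5-fold higher. The ratio was 6.39 for miR6024 and 19.96 for miR5300, the latter 12.01 (9.82 to 14.8) over all WT reads of its region. For miR6027 the leading WT RNA did not match the family, and the same region had 15.8 RPM in WT and 537 RPM in nrpd1. All 3 families that target silencing proteins were higher. The DICER-LIKE1 regulator miR162 stood at 1209 and 4789 RPM, 3.96-fold higher but lower than WT under miRNA scaling. The ARGONAUTE1 regulator miR168 was 17.7-fold and the ARGONAUTE2 regulator miR403 6.68-fold higher. Over loci matched in either genotype the miR168 ratio was 14.0 (12.8 to 15.3).

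The remaining families were miR397, miR398, miR390, miR394 and miR1919. The laccase regulator miR397 had the highest ratio, 44.1, from 12 WT reads (counting interval 24.9 to 86.1). The superoxide dismutase regulator miR398 was 20.3-fold higher, at 7.01 and 142 RPM, and miR390, which triggers siRNAs from TAS3 transcripts, was 15.9-fold higher. With loci unmatched or unlisted in WT counted in, the miR390 ratio was 10.7 (8.68 to 13.3). The ratio was 3.85 for miR394, which was lower under miRNA scaling, and 11.6 for miR1919, which was matched only in nrpd1 and compared over its region.

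**Figure D3:**
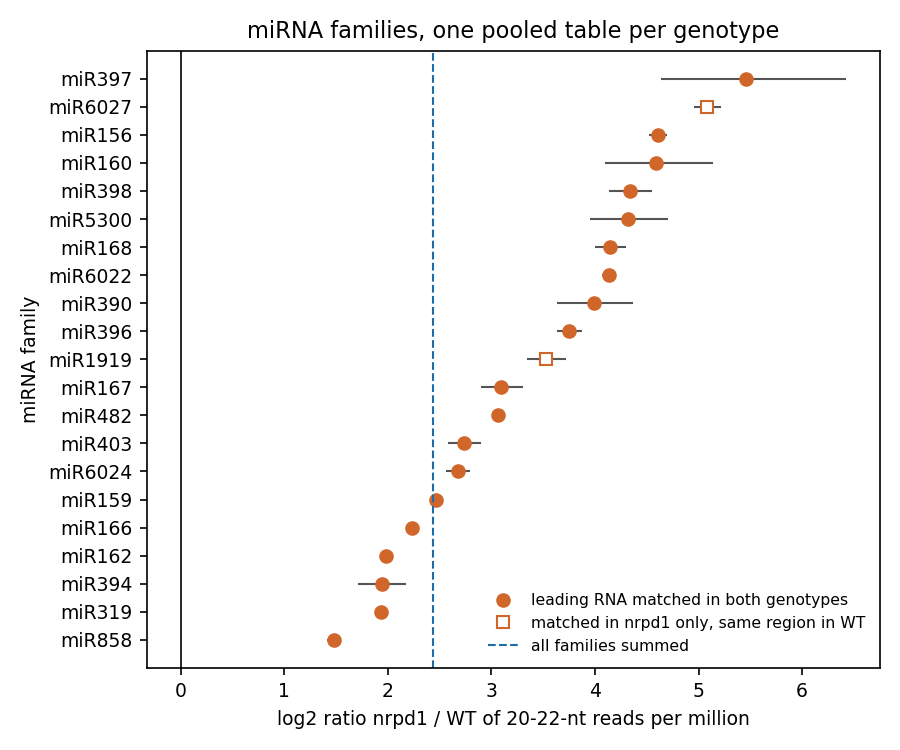
The log2 ratio nrpd1 over WT of 20–22-nt RPM (x axis) for each miRNA family with at least 10 RPM in either genotype (y axis), with bars for 95% counting intervals, open squares for families matched only in nrpd1, a solid line at equal abundance and a dashed line at the ratio of all families summed (2.44). All 21 families lie right of equal abundance by RPM, and 5 of them, lying left of the dashed line, would be lower in nrpd1 under miRNA scaling.

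Phased siRNAs are cut in register from longer double-stranded RNA and give a locus a high phase score. In nrpd1, 30 loci with Dicer call 21 and at least 10 RPM had a score above 30, against 12 in WT, which was 6.62% of the 453 such loci in nrpd1 and 10.9% of the 110 in WT. Over the 32 merged regions with a phased locus in either genotype, total reads were 8567 RPM in WT and 39296 RPM in nrpd1, 4.59-fold higher by RPM but at a ratio of 0.848 under miRNA scaling. Counted singly, 31 of the 32 regions were higher in nrpd1 by RPM and 20 under miRNA scaling. On chromosome 2 at 40632762–40633562 total reads were 529 RPM in WT and 7053 RPM in nrpd1, 13.3-fold higher, and the phase score was 304 in WT and 740 in nrpd1. The region at 40649499–40650207 on the same chromosome, 261-fold higher in nrpd1, had a phase score of 531 there. On chromosome 6 at 439100–439613 reads were 13.7-fold higher, at 263 and 3612 RPM. On chromosome 8 at 59208533–59210254 reads stood at 1970 RPM in WT and 5885 RPM in nrpd1, 2.99-fold higher. On chromosome 5 at 64537130–64539895 they were 3.24-fold higher and on chromosome 2 at 29160550–29163426 they were 4.78-fold higher, and these last 3 regions were lower in nrpd1 under miRNA scaling.

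Loci of the 21- and 22-nt classes were also more numerous in nrpd1 by RPM, and with the listing minimum applied after miRNA scaling 938 of the nrpd1 21-nt loci and 1375 of the 22-nt loci would be left. The first count is above the 642 of WT and the second under the 1529 of WT. There were 642 loci with Dicer call 21 in WT, covering 0.240 Mb at a mean of 109 RPM per kb, and 2801 in nrpd1, covering 0.963 Mb at 174 RPM per kb. Under miRNA scaling this nrpd1 mean was 32.2, lower than WT. Loci with Dicer call 22 numbered 1529 in WT, over 0.600 Mb at 34.5 RPM per kb, and 4474 in nrpd1, over 1.39 Mb at 58.5 RPM per kb. Under miRNA scaling the nrpd1 mean was 10.8, lower than WT. Of the nrpd1 21-nt loci 45.7% lay over a WT locus, and at 55.0% of those the main WT locus was called 24 nt. For 22-nt loci the shares were 52.3% and 42.7%. The 24-nt shares of 55.0% and 42.7% lie under the 95.7% of all WT loci that were called 24 nt. The leading RNA began with A at 24.5% of WT and 37.8% of nrpd1 21-nt loci, and at 18.6% and 30.8% of 22-nt loci.

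The last comparison asked whether the 24-nt difference depended on position along the chromosomes. The chromosome ends, taken as the 25% of length at either end, held 82.4% of WT 24-nt reads in loci. There 24-nt reads went from 386924 RPM in WT to 124570 RPM in nrpd1, a ratio of 0.322 (0.3215 to 0.3224). In the chromosome middles they went from 73163 to 22615 RPM, a ratio of 0.309 (0.308 to 0.310). The ratio lay between 0.300 on chromosome 7 and 0.343 on chromosome 8, and it was higher at the ends than in the middle on 9 of 12 chromosomes. The exceptions were chromosomes 7, 8 and 12. Unplaced sequence differed from the assembled chromosomes, with 9489 RPM in WT, 7779 RPM in nrpd1 and a ratio of 0.820. By RPM, 21-nt reads were 4.86-fold higher in nrpd1 at the ends and 3.22-fold higher in the middles, both lower than WT under miRNA scaling. Loci of the WT 24-nt class overlapped a listed nrpd1 locus in 49.3% of cases at the ends and 36.2% in the middles. Listing depends on abundance, as given above, and these shares were not compared at equal abundance, so they do not show a larger fall in the middles.

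**Figure D4:**
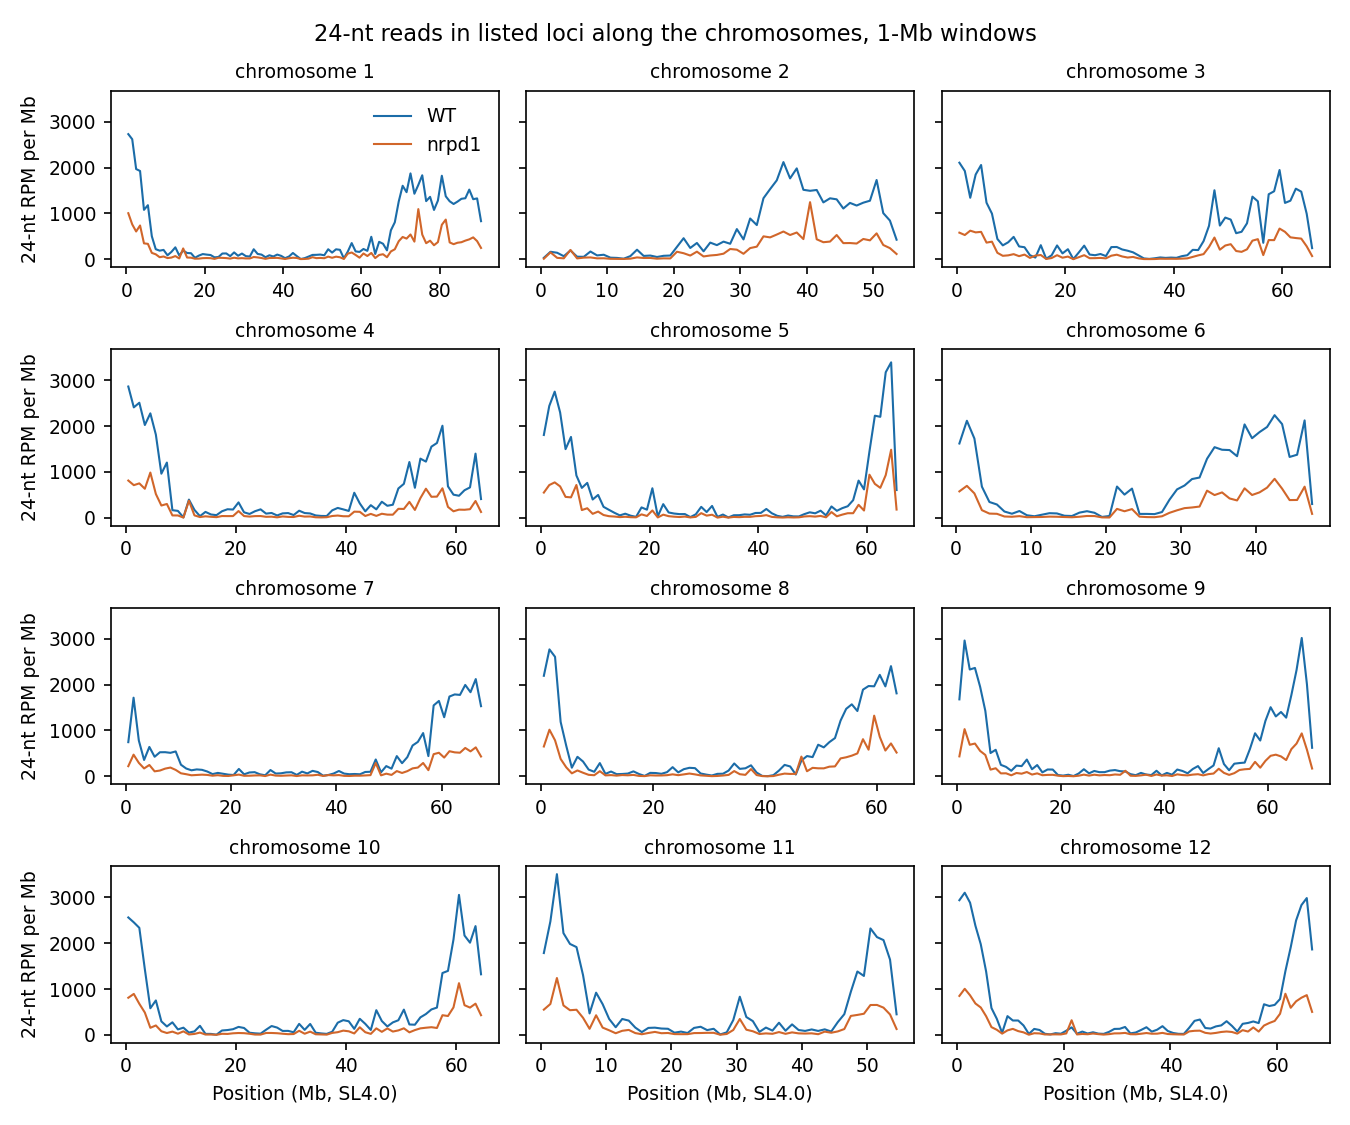
24-nt RPM in listed loci (y axis) in 1-Mb windows along chromosomes 1 to 12 (x axis, position in Mb on SL4.0), with 1 line for each genotype's pooled table. The nrpd1 line runs below the WT line in 771 of 778 windows, with ratios per chromosome between 0.300 and 0.343.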

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

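The tests on single loci in this part were chosen after the results had been seen. Reads longer than 24 nt and shorter than 20 nt had no comparison of their own beside the totals per region, and both were present in listed loci of nrpd1. The longer reads made up 33605 RPM in nrpd1 against 21481 RPM in WT. Most of that difference lay at 1 locus on chromosome 3 at 14267685–14267716, with 926 RPM in WT and 10103 RPM in nrpd1 over all read lengths, and outside it longer reads differed 1.16-fold. Its leading RNA was the 27-nt GGUGGCUGUAGUUUAGUGGUAAGAAUU. The shorter reads made up 9887 RPM in nrpd1 against 6511 RPM in WT. Loci without a Dicer call numbered 4055 in nrpd1 and 2398 in WT. As ratios of 1.56 and 1.52, the values for longer and shorter reads lie under the miRNA factor of 5.41 and would be lower in nrpd1 under that scaling.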

How the results depend on the processing

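The 8 alternatives marked here as added were chosen after the data were seen. No paired analysis was possible because the tables hold 1 pooled value per genotype and no column per library, although the labels share replicate numbers, and for the same reason count models and left-out replicates were not run. Gene lists were not run for want of an annotation on the same build. Of 37 alternatives over 15 results, 11 stayed within the counting interval or 1.5 times a count, 24 moved by more and 2 reversed. Scaling by miRNA reads reversed the 21-nt ratio to 0.816 and the 22-nt ratio to 0.515, since it divides every ratio by 5.41, took the 24-nt ratio to 0.0610, and gave 172843 lower and 192 higher merged regions. Added scaling of regions with at least 50 RPM gave 624 lower and 62 higher, and of nrpd1 loci 938 of 21 nt and 1375 of 22 nt. Keeping only loci with at least 2 RPM gave ratios of 0.278 for 24 nt, 4.67 for 21 nt and 2.98 for 22 nt, 0.265 at chromosome ends and 0.263 in the middles, 65978 WT and 21124 nrpd1 24-nt loci, and 88.3% of WT 24-nt loci still listed, fewer loci near the listing minimum being tested. That share was 31.8% when 50% of a locus had to be covered and 43.6% with nrpd1 24-nt loci only. A 2-fold threshold gave 97370 lower and 5859 higher regions. The 24-nt ratio was 0.320 on chromosomes 1 to 12 and, as an added alternative, 0.290 in regions with at least 90% unique reads in WT. Without the largest nrpd1 locus of each class, also added, the ratio was 3.94 for 21 nt and 2.62 for 22 nt. Windows of 500 kb gave 0.310 in the middles. The miRNA median stayed between 3.10 and 3.74 on the log2 scale under its 4 alternatives, of which matching in either genotype was added. Beyond the reasons given, the cause was not tested. Depth and the listing minimum limit the faint loci, as a region near that minimum cannot show a 4-fold lower value by RPM. Under miRNA scaling regions unlisted in nrpd1 could be called lower.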

Other observations

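The tests of even partial activity, of regions far under the median ratio, of the share of unique regions, of the miRNA denominator and of the listing minimum were chosen after the results had been seen, as were the regions named here. A small set of WT 24-nt regions had more 24-nt RNA in the mutant. It comprised 79 of the 11510 regions with at least 10 RPM, whose summed 24-nt reads were 1245 RPM in WT and 5042 RPM in nrpd1, a ratio under the miRNA factor of 5.41, and under miRNA scaling 12 of the 11510 regions were higher. In nrpd1 46 of them were called 24 nt, 17 were called 22 nt and 10 were called 21 nt. They were long, with a median of 1244 bases against 340 bases for all 11510.

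The most abundant region in nrpd1 was a single 21-nt RNA on chromosome 10 at 61704285–61704319, AAUGAAGACUGAUCCAAGAUC, with 441 RPM in WT and 19125 RPM in nrpd1, 43.4-fold higher. On chromosome 8 at 62456747–62458327 a 22-nt locus stood at 134 and 7628 RPM, 56.8-fold higher, with only 4.48% of nrpd1 reads mapping uniquely. The most abundant region in WT, a 22-nt locus on chromosome 4 at 4929652–4933643, stood at 5843 RPM in WT and 5436 RPM in nrpd1, a ratio of 0.930. Of the 321 WT regions called 20 to 22 nt with at least 10 RPM, 303 were higher in nrpd1 by RPM, with a median ratio of 3.03, which miRNA scaling would turn to lower. ShortStack's own miRNA call was given to 33 loci in WT and 96 in nrpd1.

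The 24-nt RNAs left in listed loci of nrpd1 amounted to 0.330 of WT by RPM and 0.0610 under miRNA scaling, and the median ratio over strong regions was 0.307 or 0.0567. Reads outside listed loci, 33.8% of mapped reads in WT and 50.1% in nrpd1, had no known length and are not covered. By RPM, multi-mapping reads placed at lost loci are argued against as the whole cause, since regions with at least 90% unique reads in WT kept a ratio of 0.290. Whatever the scaling, these regions held 64.2% of the 24-nt reads in WT loci and 56.5% in nrpd1 loci. Under miRNA scaling their ratio was 0.0536, which does not decide, because the multi-mapping reads still allowed there could reach it. Uniqueness was set on WT reads only. Of the 11510 regions 91 had an upper counting bound under 0.153, 50% of the median, where counting error alone gave 0 in each of 100 draws. Another 206 had a lower bound over 0.614, 2 times the median. Counting error around 1 ratio thus does not account for the 91. Without a spread between libraries, neither count decides whether one uniform share or activity holds for all regions. Carry-over of WT RNA, for example from surrounding tissue or from a library in the pool, and partial polymerase activity at all loci alike cannot be told apart without values per library, since both would leave strong regions listed, and the 0.1998% of regions unlisted in nrpd1 largely restates the ratio and favours neither. The cause of the 79 higher regions was not tested.

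The higher miRNA values in nrpd1 were weighed against the smaller pool of 23- and 24-nt RNAs, which raises the RPM of everything else. The largest factor this could give is 7.77, if every WT read outside listed loci were 23 or 24 nt and none in nrpd1. The lower counting bound of 12 families, miR156, miR160, miR168, miR390, miR396, miR397, miR398, miR482, miR1919, miR5300, miR6022 and miR6027, lay above it and that of the other 9 did not, with ratios of the 12 between 8.37 and 44.1 once loci unmatched or unlisted in WT were counted in. In these libraries the pool alone is thus argued against as the whole cause for the 12, while for the other 9, which the factor could reach, the pool and a difference in abundance cannot be told apart, and how much of the excess is spread between libraries is open. The place of miR159 among the 9 depends on the matching, with ratios of 5.26 here and 8.03 (7.97 to 8.09) over loci matched in either genotype. Loci hidden by the listing minimum are argued against only as the whole cause. The 5 families with nrpd1 loci unlisted in WT kept ratios of 3.82 to 23.9 by RPM with those loci counted at the minimum. For miR156 and miR319, with more WT reads, such loci could change little, while for miR160 they took the ratio from 24.1 to 10.4. A difference in embryo stage or genotype stays open, untested.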
